A study of Homo sapiens with 10 samples.

How the data were processed

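The series holds RNA-seq of laser-captured cells from human brain in multiple sclerosis. The labels sort the 10 samples into a white matter line and a grey matter line with 5 samples each. Per the series' design text, the captured cells were microglia lining either white matter lesions or subpial lesions of the cortex. Per the labels' protocols, total RNA was brought to one small fixed amount per sample, captured with oligo-dT and turned into cDNA with the SMART-Seq v4 kit, and libraries were made with Nextera XT and sequenced in paired-end mode on an Illumina instrument. Neither kit keeps the strand of the RNA, so reads of a gene and of an antisense partner could not be told apart. The marker by which cells were picked for capture is not given in the sources used here.

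The deposited table holds estimated counts per gene for each sample, without normalization by the authors as far as the values show. Between 78.3% and 90.9% of the non-zero values in a library were whole numbers, and the others carried up to 2 decimals. Per the submitters' processing notes, HISAT2, DESeq2 and the build GRCh38 were used. Versions, the counting program and the gene annotation are not given in the sources used here. Fractions of counts can come from reads shared between genes, so members of near-identical families, such as the HSPA1 and HLA genes, carry that uncertainty. The table has 58288 rows, and 95.3% of them were placed on GRCh38 through the gene names of GENCODE release 29. Rows of Y-linked genes, of X-inactivation transcripts and of HLA-DRB3, HLA-DRB4 and HLA-DRB5 were left out, 564 in all. No row lacked a gene name.

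Total counts per library ran from 618060 to 9535733. The values were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by group, robust quasi-likelihood test, two-sided, group as the single term). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. After the filter 12255 genes were tested. Fold changes are log2, white minus grey, and the standard error (SE) of each was derived as the size of the log2 fold change divided by the square root of its F statistic. CPM values use TMM library sizes. Gene lists were compared with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, again at an adjusted p under 0.05, and 28 of the 31 lists had the required 5 tested members. A list score is the mean log2 CPM of its tested members. Of the list entries, 1 was not found in the table.

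The labels do not tie samples to donors. P-values therefore measure only the spread between these samples. If regions of one donor stand within one line, the p-values are too small. If donors are shared across the lines, the unpaired test can instead give p-values that are too large. The same numbers 1 to 5 occur in both groups. The labels do not say that same-numbered samples belong together, so the numbers were not used as pairs in the main test. Residuals of same-numbered samples correlated at 0.038 to 0.286, and those of differently numbered samples at -0.202 to 0.135.

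The design, the gene lists, the naming rule and the alternatives below, apart from 1 named as added later, were fixed before the data were examined. The naming rule took the called protein-coding genes with the largest fold changes. With fewer than 5 called in a direction, it took the 8 with the smallest unadjusted p and a count of at least 10 in at least 4 samples of the higher group, and these are said not to have passed. It also took up to 4 members of each list with the smallest p. The rule took 124 genes, and the text names 41 of them. That choice was made after the values were seen, and it passed over genes whose sign turned under an alternative. Of the 124 genes, 34 had the other sign in at least 1 alternative, and none of these 34 is among the 41. A further gene of the rule is not reported here. The split of the stress list into heat shock and immediate early members was also made after the data were seen.

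Alternatives were DESeq2 size factors, no filter, a filter of 1 CPM in 5 samples, the replicate number as a block, mitochondrially encoded genes left out, the number of detected genes as a covariate, each library left out in turn, DESeq2 1.42.0, limma voom with quality weights, camera with an estimated correlation, and fry. The removal of white matter line replicate 2 and grey matter line replicate 1 together was added later. Single values per library were compared by exact permutation tests. Chance was measured with 100 of the 126 possible splits of the 10 libraries.

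The fit was tested on simulated counts for the white minus grey comparison, with 11547 genes passing the filter. It called 6.3% of 63 genes changed 4-fold, 61.9% of 63 changed 16-fold and 93.3% of 60 changed 64-fold. Of 11361 unchanged genes, 5 were called. The spread between these libraries therefore limits single-gene calls to very large changes. A list of 10 genes shifted 8-fold was called, and 0 of the 27 other lists were. The simulated genes were drawn independently of each other, so this says nothing about false list calls where genes vary together. In the real libraries the estimated correlation within a list reached 0.853.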

Results

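Gene expression was measured in microglia and macrophages captured by laser at lesion borders in multiple sclerosis, with 5 white matter line and 5 grey matter line libraries. The question was how transcripts differ between cells lining white matter lesions and cells lining subpial lesions of the cortex. White matter line replicates 1 to 5 held 9468446, 618060, 1601337, 1865158 and 4890704 counts, and grey matter line replicates 1 to 5 held 9535733, 2231903, 5960675, 2695391 and 7287116. White libraries had 14402 ± 4927 genes with at least 1 count and grey libraries 16394 ± 1714 (SD, n = 5 each), a difference within the spread (exact permutation p = 0.468, two-sided). White matter line replicate 2 had 7183 such genes, and the other white libraries had at least 13055. Mitochondrially encoded mRNA took 12.3 ± 6.74% of counts in white and 15.5 ± 11.3% in grey libraries (SD, n = 5 each; exact permutation p = 0.635, two-sided), and the smallest p this test can give is 0.00794.

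Every library held RNA of other brain cells beside that of microglia. Oligodendrocyte and myelin genes took 4.88 ± 2.44% of non-mitochondrial counts in white and 3.48 ± 2.55% in grey libraries, and astrocyte genes took 1.98 ± 0.360% and 2.29 ± 1.07% (SD, n = 5 each). Genes of the microglia and macrophage core list took 0.0854 ± 0.0672% and 0.0510 ± 0.0246%. Pan-neuronal genes ranged from 0.0454% to 1.02% over the 10 libraries. Grey matter line replicate 1 stood apart in myelin RNA: MBP, the gene of myelin basic protein, was at 202 CPM there, against 8009 to 34700 CPM in the other grey libraries. The homeostatic markers P2RY12 and TMEM119 had too few counts to be tested.

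**Figure D1:**
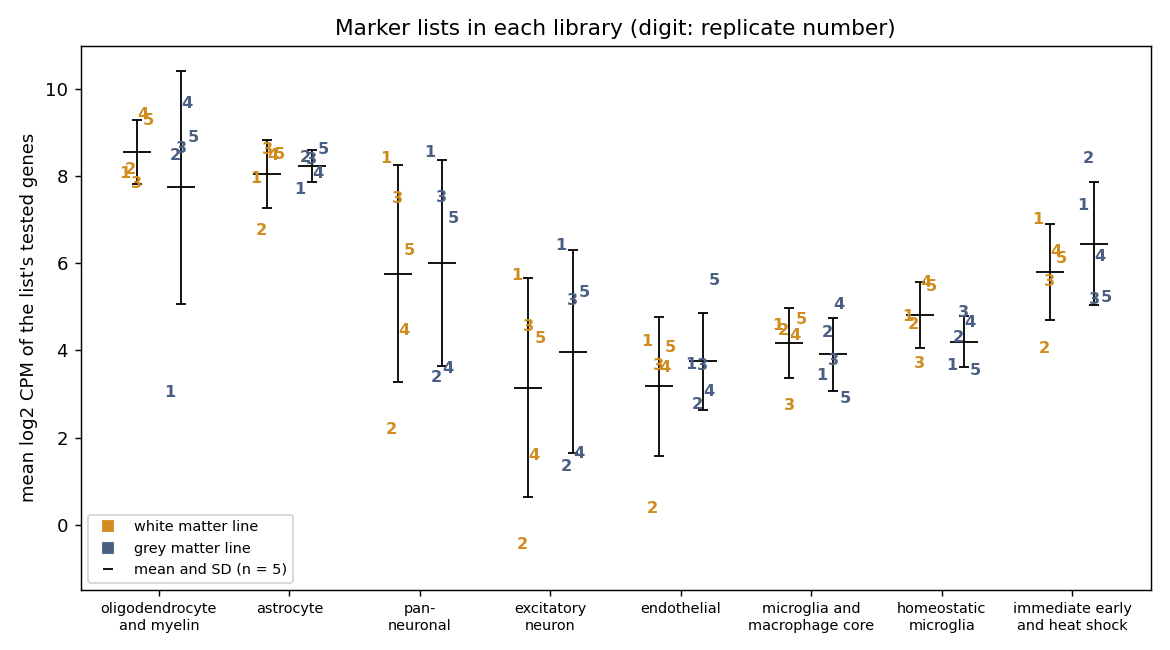
Mean log2 CPM of the tested genes of 8 marker lists (vertical axis) in each library, drawn as its replicate number, with the mean and SD of each group of 5. Grey matter line replicate 1 lies at 3.04 in the myelin list while the other grey libraries lie between 8.48 and 9.68. White matter line replicate 2 lies lowest in the astrocyte, pan-neuronal, excitatory neuron, endothelial, and immediate early and heat shock lists.

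No single gene passed the test between the lines. Values are given for the 8 genes with the smallest p in each direction among protein-coding genes with at least 10 counts in at least 4 libraries of the higher group. On the white side RGS1, a regulator of G protein signalling in leukocytes, had a log2 fold change of 3.10 ± 0.859 (SE), with 271 ± 323 CPM in white and 31.6 ± 28.7 CPM in grey libraries (SD, n = 5 each). SLC2A5, the fructose transporter typical of microglia, differed by 2.96 ± 0.867 (SE), SRGN, the granule proteoglycan serglycin, by 2.81 ± 0.851, and ZFP36, an RNA-binding protein that limits cytokine mRNA, by 2.24 ± 0.721. COL7A1, a collagen gene on chromosome 3 (48564073 to 48595267, GRCh38), had the smallest p of all, with 44.0 ± 42.1 CPM in white and 2.40 ± 1.65 CPM in grey libraries and a log2 fold change of 4.20 ± 1.14 (SE). ALDH1A2, which makes retinoic acid, ANGEL1 and IL4R, a chain of the interleukin 4 receptor, completed these 8 genes at 4.90, 2.71 and 4.10. For these last 3 genes white matter line replicate 2 was the highest white library. IL4R was at 290.4 CPM there against 4.43 to 6.17 CPM in the other white libraries, and ALDH1A2 at 167.3 CPM against 1.12 to 16.3 CPM. Without that library the log2 fold change was 0.53 for IL4R, 1.41 for ANGEL1, 3.05 for ALDH1A2 and 2.06 for SLC2A5, and without white matter line replicate 1 it was 2.06 for RGS1.

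On the grey side HSPH1, a heat shock protein of the HSP110 family, had a log2 fold change of -2.54 ± 0.705 (SE), with 127 ± 48.3 CPM in white and 742 ± 812 CPM in grey libraries (SD, n = 5 each). DNAJB1 differed by -2.47 ± 0.847 (SE), BAG3 by -2.93 ± 1.03, HSPA4L by -2.67 ± 0.949 and PTGES3, a cochaperone of HSP90, by -1.75 ± 0.588. SESN2, a stress-induced regulator of metabolism, lay at -4.35, the transcription factor gene ATOH8 at -3.56 and the centromere gene CENPO at -3.68. HSPH1 reached 1721 and 1535 CPM in grey matter line replicates 1 and 2 and 118 to 175 CPM in the other grey libraries. Without grey matter line replicate 2 BAG3 differed by -1.39, PTGES3 by -0.98, DNAJB1 by -1.68 and ATOH8 by -2.32. By edgeR's quasi-likelihood test 0 of 12255 genes passed adjustment, with a smallest adjusted p of 0.9997. An unadjusted p under 0.05 was reached by 238 genes (1.94%), 143 of them higher in white. DESeq2 called 4 genes, COL7A1 among them, limma voom called 0, and edgeR without a filter on low counts called 14. In that last fit 14.24% of 26352 genes had an unadjusted p under 0.05. The median log2 fold change of all tested genes was -0.13.

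**Figure D2:**
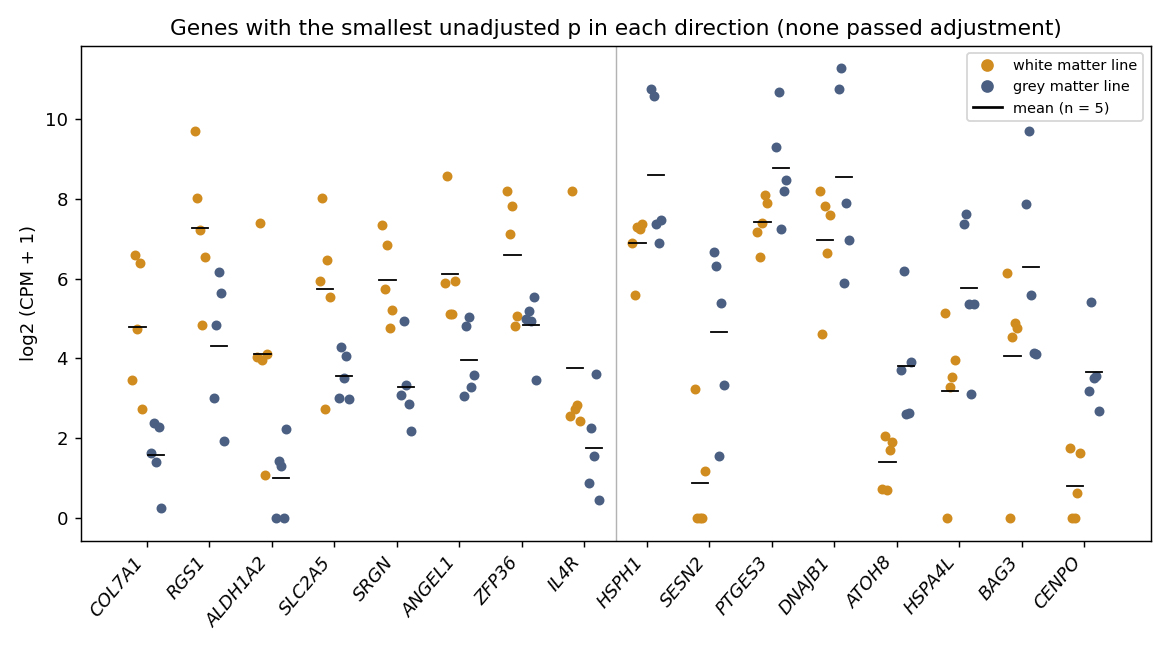
Log2 (CPM + 1) in each library (points) and group means (bars, n = 5) for the 8 genes with the smallest unadjusted p in each direction, higher in white to the left of the line and higher in grey to the right. None passed adjustment, and for IL4R, ANGEL1 and ALDH1A2 1 white library lies far above the other 4.

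Across the fixed lists, 8 passed camera's test with its preset correlation, all toward the white matter line, and 0 passed with an estimated correlation or by fry. Camera asks whether a list is shifted against the other tested genes. The mean log2 CPM of all tested genes differed by -0.482 (white minus grey), so a call toward white is relative to that lower background. It does not test whether the list itself lies above grey. Fry does test each list by itself. The medians come from edgeR's fit and not from camera. Of 15 tested Fc receptor and phagocytosis genes 14 lay higher in white (median log2 fold change 0.87, adjusted p = 0.00694, and adjusted p = 0.191 with an estimated correlation). Among them SYK, a kinase downstream of Fc receptors, differed by 3.72 ± 1.35 (SE), FCER1G, their signalling chain, by 2.48 ± 0.913, FCGR1A by 2.41 ± 1.18 and the scavenger receptor gene MSR1 by 1.69 ± 0.976. The first 3 of these were highest in white matter line replicate 2, with SYK at 230.4 CPM against 0 to 34.2 CPM in the other white libraries. Without it SYK differed by 1.52, FCER1G by 1.48 and FCGR1A by 0.65, and without white matter line replicate 3 MSR1 differed by 0.62. Of 10 homeostatic microglia genes 8 lay higher in white (median 0.96, adjusted p = 0.00444, and adjusted p = 0.191 with an estimated correlation), with GPR34 at 1.44 ± 0.973 (SE) and CSF1R, the receptor that microglia need to survive, at 1.09 ± 0.852, or 0.37 and 0.60 without white matter line replicate 2. Adjusted over the list alone, SLC2A5 passed in edgeR's quasi-likelihood test (adjusted p = 0.0236), as did no other member of the 31 lists. With a separate adjustment in each of 31 lists, a single pass can arise by chance. Over all genes tested the adjusted p of SLC2A5 was 0.9997.

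Of 16 iron handling genes 11 lay higher in white (median 0.47, adjusted p = 0.0036, and adjusted p = 0.191 with an estimated correlation). HAMP, the gene of the iron hormone hepcidin, differed by 4.03 ± 1.45 (SE), SLC11A1, a metal transporter of phagosomes, by 3.08 ± 1.03 and TFRC, the transferrin receptor, by 1.68 ± 0.675. HMOX1, which breaks down haem, lay the other way at -2.40 ± 1.05. Without white matter line replicate 2 SLC11A1 differed by 1.43 and HAMP by 3.15, and without grey matter line replicate 2 HMOX1 differed by -1.27. As a share of non-mitochondrial counts the list was 1.99% in white and 2.20% in grey libraries, the opposite order to its median. Of 12 MHC class II genes 10 lay higher in white (median 0.84, adjusted p = 0.00695, and adjusted p = 0.567 with an estimated correlation), with HLA-DMB at 2.09 ± 0.809 (SE), HLA-DRA at 1.37 ± 0.662 and CD74 at 0.72 ± 0.594. Without white matter line replicate 2 HLA-DMB was at 1.12 and CD74 at 0.43, and without white matter line replicate 1 HLA-DRA was at 0.90. Of 14 MHC class I and peptide loading genes 12 lay higher in white (median 0.40, adjusted p = 0.0187, and adjusted p = 0.567 with an estimated correlation), TAP1 at 1.04 ± 1.11 (SE) among them, or 0.57 without white matter line replicate 5.

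Cholesterol and lipid handling genes lay higher in white in 12 of 18 cases (median 0.47, adjusted p = 0.0278, and adjusted p = 0.766 with an estimated correlation), with APOE, the main lipid carrier of the brain, the other way at -0.62 ± 0.508 (SE), or -0.32 without grey matter line replicate 2. Their share of non-mitochondrial counts was 0.302% in white and 0.350% in grey libraries, the opposite order to the median. The microglia and macrophage core list had 10 of 14 genes higher in white (median 0.35, adjusted p = 0.0312, and adjusted p = 0.766 with an estimated correlation). Its members LAPTM5 and C1QA differed by 1.80 ± 0.819 and -1.27 ± 0.907 (SE). LAPTM5 differed by 0.23 without white matter line replicate 2, where it was at 479.8 CPM against 24.6 to 56.1 CPM in the other white libraries, and C1QA by -0.69 without grey matter line replicate 2. The list of oligodendrocytes and myelin had the smallest p of all (9 of 15 genes higher in white, adjusted p = 0.00084, and adjusted p = 0.766 with an estimated correlation), although its median log2 fold change was 0.08 and MBP differed by 0.53 ± 0.755 (SE), or 0.19 without white matter line replicate 4. Without grey matter line replicate 1 its median was -0.27 with an adjusted p of 0.924.

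**Figure D3:**
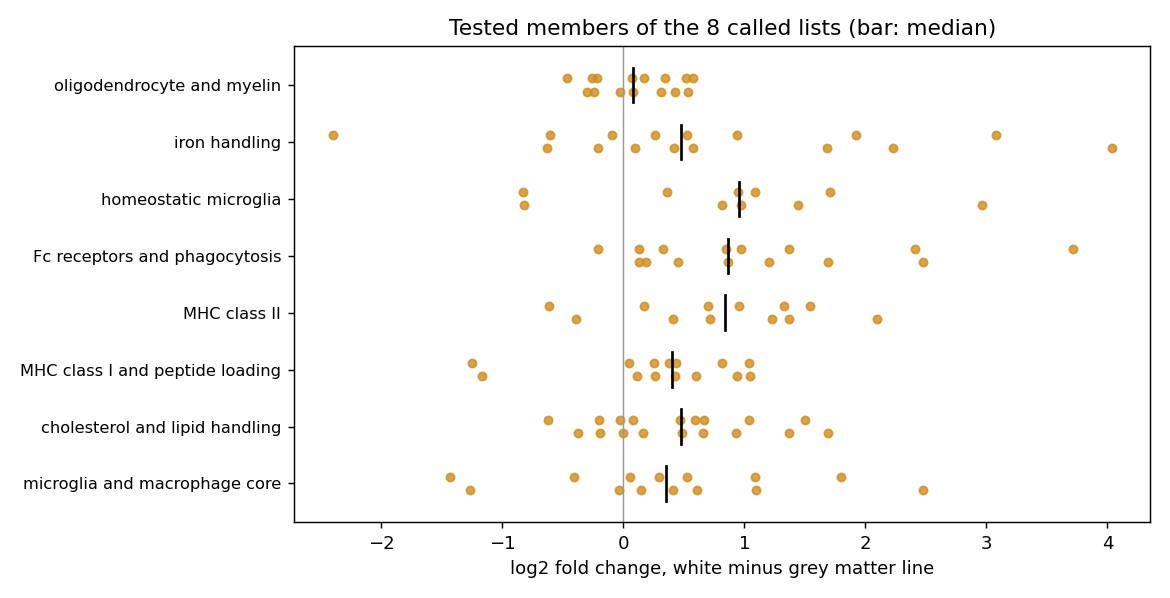
Log2 fold changes, white minus grey matter line (horizontal axis), of the tested members (points) of the 8 lists that passed camera's test with a preset correlation, with each list's median (bar). The median lies at 0.96 for homeostatic microglia and at 0.08 for oligodendrocytes and myelin.

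The called lists share members, so their calls are not independent. FCER1G is in the Fc receptor and core lists, and CSF1R in the homeostatic and core lists. MSR1 is in the Fc receptor and cholesterol lists, and TF in the iron and myelin lists. Most calls depended on single libraries. Of the 10 removals of 1 library, 8 lost at least 1 of the 8 calls, and between 4 and 8 were kept. Only the homeostatic microglia and iron handling lists were called in all 10, with medians from 0.41 to 1.39 and from 0.19 to 0.69. The core list was called in 4 of the 10 (medians from 0.06 to 0.96) and the cholesterol list in 5 (0.21 to 0.54). MHC class II was called in 8 (0.60 to 1.25), MHC class I in 8 (0.16 to 0.50) and the Fc receptor list in 9 (0.42 to 1.47). Without white matter line replicate 2, the shallowest, 4 of the 8 were called, and without grey matter line replicate 1 also 4. With both left out, an alternative added after the data were seen, 0 of the 8 were called, and the single called list was the pan-neuronal one, higher in white (median 0.97, adjusted p = 0.0164). With an estimated correlation, in the test on all 10 libraries, that list had an adjusted p of 0.881.

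The other lists did not pass. The interferon response had 12 of 17 genes higher in white (median 0.56, adjusted p = 0.0692), IFIT1 at 1.25 ± 0.899 (SE) among them. It passed in 5 of the 10 removals of 1 library, but had an adjusted p of 0.874 with an estimated correlation and 0.945 by fry. The lipid-associated and disease-associated microglia list had 12 of 19 genes higher in white (adjusted p = 0.0882) and passed in 3, with 0.842 at an estimated correlation. The heat shock and immediate early list had 9 of 13 genes higher in grey (adjusted p = 0.77), and the list of NADPH oxidase and oxidative stress 9 of 12 (adjusted p = 0.415), with NQO1 at -1.82 ± 0.905 (SE), or -0.85 without grey matter line replicate 2. Excitatory neuron genes were higher in grey in 10 of 11 cases (median -0.52, adjusted p = 0.676), but without grey matter line replicate 1 their median was 0.31. The list score was lower in white at each replicate number, though only at 1.59 against 1.62 for number 4. Whether the numbers mark pairs is not known. NEUROD6 among the excitatory neuron genes was at -1.56 ± 1.31 (SE). Inhibitory neuron genes were higher in grey in 7 of 8 cases (median -0.625, adjusted p = 0.415), with medians from -1.323 to -0.101 with 1 library left out. Pan-neuronal genes were split, 6 higher in white and 7 in grey (adjusted p = 0.415), with MAP2 at -0.55 ± 0.635 (SE), or -0.15 without grey matter line replicate 3. Astrocyte genes were split 6 to 7 (adjusted p = 0.438), with CLU at -0.78 ± 0.559 and SLC1A2 at -1.09 ± 0.804 (SE). CLU was at -0.14 without grey matter line replicate 2 and SLC1A2 at -0.56 without grey matter line replicate 5. The remaining 12 tested lists, among them complement, lysosome, glycolysis and ribosomal protein genes, had adjusted p-values from 0.0898 to 0.991.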

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

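The tests that weigh explanations here were chosen after the results were seen. A library was listed when its gap to the nearest other library of its group exceeded 0.71 of the group's range. Of 144 groups of 5 values, 32 were listed, where chance gives about 1 in 20 for values with a normal spread. That rate does not apply to the 82 groups of CPM values, 25 of them listed, since these are not on a log scale and their genes were partly picked by small p. Among the 62 groups of list scores and library values 7 were listed. White matter line replicate 2 accounts for 15 and grey matter line replicate 2 for 8.

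White matter line replicate 2 lay low in 5 list scores. These were cholesterol and lipid handling (2.97), NADPH oxidase and oxidative stress (2.83), the nuclear genes of the mitochondrial respiratory chain (4.58), TGF-beta signalling (1.94) and endothelial genes (0.358), each a mean log2 CPM. Undetected members pull such a mean down, so a low score need not be a low share of counts. Of non-mitochondrial counts, TGF-beta genes took 0.0788% there, the highest of all libraries. NADPH oxidase genes (0.135%) and endothelial genes (0.0230%) took the lowest shares of all libraries. It lay high in 10 genes. They were LAPTM5 (479.8 CPM), IL4R (290.4 CPM), ANGEL1 (380.4 CPM), ALDH1A2 (167.3 CPM), SYK (230.4 CPM), FCGR1A (430.9 CPM), SLC11A1 (639.2 CPM), HLA-DMB (273.0 CPM), GPR34 (107.3 CPM) and C1QA (55.2 CPM). Among the other white libraries LAPTM5 reached at most 56.1 CPM and FCGR1A at most 67.3 CPM.

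Grey matter line replicate 2 lay high in BAG3 (824.5 CPM), HSPB1 (1597 CPM), HMOX1 (156.0 CPM), NQO1 (272.4 CPM), CLU (8334 CPM), ATOH8 (71.9 CPM), CENPO (42.0 CPM) and SRGN (29.4 CPM). Grey matter line replicate 4 lay high in HAMP (23.7 CPM) and LAPTM5 (100.1 CPM). White matter line replicate 1 lay high in RGS1 (828.6 CPM), SESN2 (8.34 CPM) and CLU (4269 CPM). White matter line replicate 3 lay high in MSR1 (136.1 CPM) and low in the microglia and macrophage core list (2.74). White matter line replicate 4 lay high in APOE (2098 CPM), and grey matter line replicate 1 low in the oligodendrocyte and myelin list (3.04).

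For the 8 lists called toward the white matter line, chance was not excluded: 28 of 100 splits of the 10 libraries called at least 8 lists, and the highest other split called 17. For single genes the splits say nothing about chance: the real split called 0, so all 100 splits called as many, and the highest other split called 1. Leaving out white matter line replicate 2 and grey matter line replicate 1 kept 0 of the 8 lists, and none of the other 24 pairs of one white and one grey library kept fewer than 2. Depth is a candidate source as well: the mean log2 CPM of all tested genes differed by -0.48 (white minus grey), and by -0.064 without the shallowest library, which kept 4 of the 8 lists. Fewer counts are not the only difference. With every library thinned to the smallest total, the lowest white library had 7207 detected genes, against at least 12719 in grey. Without grey matter line replicate 1 the difference stayed at -0.471, yet 4 of the 8 lists were kept, so depth does not cover that loss. A difference between the lesion types stays open and was not separated from these explanations. The fits also held no term for the amount of microglial RNA in a library. The core list took 0.0854 ± 0.0672% of non-mitochondrial counts in white and 0.0510 ± 0.0246% in grey libraries (SD). A difference in expression within the cells was therefore not separated from one in microglial RNA content.

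Heat shock genes were high in some grey libraries. Their score was 10.7 in grey matter line replicate 2 and 8.98 in replicate 1, against 5.60 to 7.23 in the other grey libraries and at most 7.40 in the white ones. The median log2 fold change over the 6 members was -1.53, but these were split from their fixed list after the values were seen and not tested as a group, and neither the list (adjusted p = 0.77) nor any member passed. A general stress response that also moves immediate early genes cannot be told apart. The median of those 7 members was 0.075, with an SD of 0.45 over them, but their score was also highest among the grey libraries in grey matter line replicates 2 (6.48) and 1 (5.91), against at most 5.22 in the other grey libraries and 2.04 to 7.02 in the white ones. A single library may account for most of the heat shock median, since without grey matter line replicate 2 it was -0.291. Among the members named here, HSPB1 fell from -1.97 to -0.65 with the same library left out. BAG3 fell from -2.93 to -1.39 and DNAJB1 from -2.47 to -1.68. A difference between the lesion types was not separated from this.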

How the results depend on the processing

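The removal of 2 libraries together was chosen after the data were seen. The count of called genes was 0 in the main test and in all alternatives except no filter on low counts, which called 14, and DESeq2, which called 4. It stayed at 0 with any 1 library left out. Called lists numbered 8 in the main test, 5 without a filter, 1 with both libraries left out, and 0 with an estimated correlation and 0 by fry. Leaving out 1 library gave 5 to 11 lists. Of the 8, between 4 and 8 were kept with 1 library left out, and 0 with both. The cause was not tested. The oligodendrocyte and myelin list turned, to a median of -0.271 without grey matter line replicate 1 (range -0.271 to 0.466 with 1 library left out) and -0.265 without both libraries. Its median was also negative without white matter line replicate 4 (-0.165) or 5 (-0.034), where the test still called the list toward white. Of the 20 lists not called, 16 had a median of the other sign in at least 1 such removal and 6 were called in at least 1. The replicate block, the 1 CPM filter and leaving out mitochondrial genes each called 9 lists, the added one being the interferon response (median 0.173 with the block; adjusted p 0.0403, 0.0431 and 0.0341), which with an estimated correlation had 0.874. The covariate for detected genes kept 6 of the 8, losing the core list (0.291) and MHC class I (0.076). It added the interferon response and the pan-neuronal list toward white and the mitochondrially encoded list toward grey (0.0192 each). With an estimated correlation in the main test, the last 2 had 0.881 and 0.939. The mitochondrially encoded list was also called without white matter line replicate 2 (0.0205). The residuals of same-numbered samples correlated at 0.286, 0.093, 0.115, 0.118 and 0.038, against -0.202 to 0.135 for differently numbered samples. White matter line replicate 2 correlated best with grey matter line replicate 4, and white matter line replicate 5 had 0.038 with grey matter line replicates 3 and 5. Residuals sum to 0 within each line, which holds the average of these correlations near 0. These values do not settle whether the numbers mark pairs. The block gave sign-flip p-values of 0.75 for the mitochondrial share and 0.375 for detected genes. For the total count it gave 0.0625, the smallest that 32 sign flips allow, with the white library lower in all 5 numbers, where the exact permutation p was 0.397. The difference in the mitochondrially encoded share of counts ranged from -5.81 to 1.26 percentage points with 1 library left out, and that in detected genes per library from -3459.8 to -186.8. The 41 named genes kept their direction in all 777 alternative fits, but they were picked with that in view: over all 124 genes of the rule, 79 of 2335 fits had the other sign, in 34 genes. Leaving out 1 library took the log2 fold change below 0.5 of its value in 13 of the 41, in 6 of them most without white matter line replicate 2 and in 4 without grey matter line replicate 2. Past the threshold were COL7A1 with DESeq2 and RGS1, HSPH1 and DNAJB1 without a filter. At this depth and spread the simulated fit called 6.3% of 4-fold changes, so moderate changes in single genes were not detectable.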

Other observations

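The tests in this part were chosen after the values were seen. Neuronal RNA differed more within each line than between them. The pan-neuronal score, a mean log2 CPM, was 8.41, 2.18, 7.50, 4.45 and 6.29 in white matter line replicates 1 to 5 and 8.56, 3.38, 7.52, 3.60 and 7.02 in grey matter line replicates 1 to 5. White matter line replicate 2 had the lowest score but not the lowest share of non-mitochondrial counts. Its share was 0.132%, against 0.0454% in grey matter line replicate 4.

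Library depth alone is argued against, because with every library thinned to the smallest total the range of the score over the 10 libraries was 5.0. At full depth it was 6.38. The thinned score used all list members, no TMM and another offset, so the drop between the 2 ranges does not measure an effect of depth. Same-numbered samples may share their tissue content, for example through a shared donor or block. Their scores differed by 0.591 on average, against a median of 2.41 over the 120 pairings (exact permutation p = 0.0083, the smallest these pairings can give). This list was singled out as the most extreme of 28, and its adjusted p of 0.156 did not pass. A single list at the smallest possible p cannot pass adjustment over 28 lists, so that outcome decides nothing. Shared tissue content stays a hypothesis. Swapped labels cannot be told apart from this either: 2 white libraries lie above and 2 grey libraries below the median score. Those white libraries, replicates 1 and 3, had myelin scores of 8.06 and 7.85. Those grey libraries, replicates 2 and 4, had 8.48 and 9.68. A swap would give this order, but it arises by chance with a probability of 0.167, and the samples are too few to decide. The lesion type as a biological explanation was not tested for this pattern.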
